A study of Homo sapiens with 12 samples.

How the data were processed

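Poly(A) RNA of MDA-MB-468 cells in 4 groups of 3 libraries was used (DMSO, ipatasertib, tazemetostat and both). Per the labels, RNA was extracted with the RNeasy Plus kit and libraries were made with Kapa Hyper Prep. The authors deposited raw read counts per gene symbol for each library. The submitters' processing notes list STAR, SAMtools, HTSeq and DESeq2 and the build hg19, without versions; the annotation, the strand setting and the order of steps are not given in the sources used here. The authors also deposited a table of normalized signal in which each column equals the counts of 1 library divided by a constant; this held for 100% of 23202 genes in each library at a tolerance of 0.001, and the table was used only for that check. In it, 26 gene names of 23228 did not match the count tables. No coordinates are given, since the reference at hand is of another build.

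Each count table held 23228 genes, 3351 of them without a read in any library. The closing lines that name no gene were kept out of library sizes and tests; they took the rest of the counted total, and genes took 66.3% ± 1.66 of it with DMSO, 63.24% ± 0.637 with ipatasertib, 66.23% ± 0.98 with tazemetostat and 61.9% ± 1.38 with the combination (SD, n = 3). Totals of 12981622 to 28746965 counts per library in genes put 3 counts at 0.104 to 0.231 CPM. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

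The counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10), TMM factors, 1 fit over the 12 libraries with a mean per group and 8 residual degrees of freedom, robust quasi-likelihood F-tests and Benjamini-Hochberg adjustment, with a threshold of 0.05 over 14571 genes. The 6 comparisons were each drug and the combination against DMSO, the combination against each drug, and the interaction. CPM values use the TMM-scaled totals. A fold against a group with no read is a bound against 3 counts over the group, and a ratio against 1 to 3 counts has a 95% counting interval.

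A total of 31 gene lists were fixed before the data were examined, as were the groups, the designs, the rule for naming genes and all but 1 of the other settings. The lists are genes under FOXO control, receptor tyrosine kinases, MAPK output, cholesterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, DNA replication, mitosis, ribosome biogenesis, the amino acid and ATF4 response, lysosome and autophagy, luminal and basal mammary markers, milk and secretory genes, mammary involution, the BCL-2 family, interferon-stimulated, NF-kB and cytokine genes, MHC class I and II, developmental Polycomb targets, EZH2-silenced tumour genes, PRC2 subunits, epidermal differentiation, extracellular matrix, stress and heat shock, mitochondrially encoded genes, and markers of fibroblasts, leukocytes and endothelium as other cell types. The mitochondrially encoded list had no tested member and is not analysed here. Each list was tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists and comparisons together, and again with the correlation estimated. Members were counted by the adjustment over all genes and by one over the list alone.

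Named genes were a panel of 19, the 8 largest rises and falls against DMSO and the 6 largest in the other comparisons (adjusted p under 0.05, at least 5 CPM in the highest group, replicates not overlapping except for the interaction, a gene symbol as name), and up to 4 members of each list that passed camera or had at least 50% of its members changed in 1 direction. Part of these are printed, and some named genes are not reported here. The levels of 8 abundant transcripts of other cell types and of genes in the tests of explanations were looked up besides.

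The procedure was tested on simulated counts in which a seeded set of genes changed by known folds. For ipatasertib against DMSO over 13803 genes, it recovered 36.7% of genes changed 1.25-fold, 89.8% at 1.5-fold, 97.9% at 2-fold and 100% at 4-fold, with 3 false calls of 158. For the interaction it recovered 17.8%, 55.1%, 76% and 93.9%, with 3 false calls of 122. Only 46 to 49 changed genes per fold were tested for ipatasertib, and 45 to 50 for the interaction. The real comparisons called far more genes, so these rates do not test scaling or calling at that extent of change. Alternatives were RLE factors, library totals, DESeq2 1.42.0, no filter, a filter of 50 counts in 3 libraries, the 2 groups of a comparison alone, the replicate letter as a block, each library left out, fry, an estimated correlation and a threshold of 1 on the log2 scale. A fit without the A library of every group was added after seeing the data. The correlation of deviations from the group means was over the bound of 0.1 for pairing in 3 of 3 same-letter pairs of ipatasertib and DMSO. Only 1 of 3 of these matched its own letter best. In no other comparison did all pairs pass the bound, so the fit over the 12 libraries has no block.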

Results

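Poly(A) RNA was sequenced from MDA-MB-468, an established triple-negative breast cancer line of basal type. Cells received DMSO, ipatasertib (an inhibitor of the kinase AKT), tazemetostat (an inhibitor of EZH2, the methyltransferase of the repressive Polycomb complex PRC2), or both drugs, each drug at 5 µM. Each of the 4 groups holds 3 libraries, named A, B and C, and 12 libraries were used in all. Tazemetostat or DMSO was given from day -5, ipatasertib was added on day 0 in medium with 2% serum, and RNA was collected 24 h later. The comparisons ask what each inhibitor changed, what the pair changed, and where the effect of the pair departed from the sum of the single effects.

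Reads counted in genes ranged from 22682755 to 28746965 per library with DMSO and 18926477 to 25468348 with ipatasertib. They ranged from 19023947 to 26070000 with tazemetostat and 12981622 to 17948209 with the combination. A level of 3 counts in a library corresponds to 0.104 to 0.231 CPM, so the combination libraries have the highest detection limits. Levels below are CPM as mean ± SD with n = 3 libraries per group. The first principal component held 54.8% of the variance over 10217 genes and ran from the DMSO libraries (-29.57 to -27.79) to the combination libraries (28.03 to 32.01). The second held 28.5% and parted the ipatasertib libraries (21.48 to 22.28) from the tazemetostat libraries (-22.1 to -20.34).

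Reads assigned to no counted feature are called reads outside genes here and below. The feature type of the counting is not given in the sources used here, so they can include reads in introns of annotated genes. They made up 19.85% ± 1.43 of the counted total with DMSO and 23.26% ± 1 with ipatasertib. The share was 21.13% ± 1.64 with tazemetostat and 25.21% ± 0.952 with the combination (SD, n = 3). Against DMSO the exact two-sided permutation p was 0.1 for ipatasertib and for the combination, the smallest value that 3 against 3 libraries allow, and 0.5 for tazemetostat. Library A stood apart from B and C in each group: the chi-square per degree of freedom between B and C was 2.42 to 3.64, and between A and either of them 4.38 to 15.7. The labels do not say that A, B and C came from separate cultures, so the p-values measure the spread between these libraries, which can be technical. Genes with close copies, such as members of the PSG, KLK, HLA, S100A and keratin families, CTSL1, FKBP9L, HSPE1 and HSP90AA1, are uncertain, because reads can be lost or shared between copies. Genes that overlap another gene or have an antisense partner are uncertain too, since the strand setting of the counting is not given in the sources used here.

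With ipatasertib alone, genes that FOXO transcription factors activate when AKT is inactive rose as a group, and receptor tyrosine kinase genes and target genes of the MAPK pathway rose with them. In the FOXO list 15 of 21 tested members rose and 1 fell (16 and 2 adjusted over the list alone). The FOXO median log2 fold change was 0.705, camera adjusted p = 6.54e-17, adjusted p = 0.0051 with an estimated correlation. PIK3IP1, which restrains PI3K, rose from 13.3 ± 1.4 to 61.3 ± 2.98 CPM (log2 fold change 2.20 ± 0.091 SE, edgeR adjusted p = 4.76e-14). IRS2, an adaptor of the insulin and IGF1 receptors, rose from 28.3 ± 1.58 to 84 ± 2.43 CPM (log2 fold change 1.57 ± 0.076 SE, edgeR adjusted p = 6.17e-13). YPEL3 (2.03) and FBXO32 (1.29) rose as well (log2 fold changes in parentheses). Of the receptor tyrosine kinase genes, 15 of 22 tested members rose (16, and 1 fell, adjusted over the list alone). The receptor kinase median log2 fold change was 0.636, camera adjusted p = 8.78e-10, adjusted p = 0.037 with an estimated correlation. IGF1R rose from 37.2 ± 0.392 to 88.3 ± 5.01 CPM (edgeR adjusted p = 5.43e-12), and MET (1.10), INSR (1.07) and ERBB3 (0.78) rose too. In the MAPK list, 14 of 18 tested members rose and 1 fell (14 and 1 adjusted over the list alone). The MAPK median log2 fold change was 0.807, camera adjusted p = 4.28e-17, adjusted p = 0.0051 with an estimated correlation. The ETS factors ETV5 (1.97), ETV4 (1.94) and ETV1 (1.68) and the feedback inhibitor SPRY4 (1.70) led it.

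Genes of lipid synthesis and of DNA replication fell with ipatasertib. Of the cholesterol synthesis genes, 21 of 23 tested members fell (21 adjusted over the list alone). The cholesterol synthesis median log2 fold change was -0.453, camera adjusted p = 4.5e-12, adjusted p = 0.0051 with an estimated correlation. INSIG1, which holds back the sterol sensor SCAP, fell from 264 ± 6.48 to 139 ± 10.3 CPM (log2 fold change -0.93 ± 0.072 SE, edgeR adjusted p = 1.2e-09), and STARD4 (-1.02), MVD (-0.91) and EBP (-0.82) fell too. Of the fatty acid synthesis genes, 2 of 14 tested members rose and 8 fell (2 and 8 adjusted over the list alone). The fatty acid synthesis median log2 fold change was -0.449, camera adjusted p = 0.000724, adjusted p = 0.0287 with an estimated correlation. SCD, the desaturase that makes oleate, fell from 3430 ± 81.2 to 1690 ± 95.8 CPM (log2 fold change -1.02 ± 0.062 SE, edgeR adjusted p = 1.98e-11). Of the DNA replication genes, 1 of 28 tested members rose and 23 fell (1 and 23 adjusted over the list alone). The DNA replication median log2 fold change was -0.454, camera adjusted p = 1.36e-10, adjusted p = 0.0127 with an estimated correlation. RRM2, a subunit of ribonucleotide reductase, fell from 394 ± 7.57 to 158 ± 6.06 CPM (log2 fold change -1.32 ± 0.072 SE, edgeR adjusted p = 4.39e-12), and CCNE2 (-1.05), CDC6 (-0.91) and E2F1 (-0.79) fell with it. Of the mitosis genes, 20 of 24 tested members fell (20 adjusted over the list alone). The mitosis median log2 fold change was -0.316, camera adjusted p = 4.98e-06, adjusted p = 0.196 with an estimated correlation. CDK1 (-0.68) and CCNA2 (-0.65) fell. Glycolysis and oxidative phosphorylation were lower with the preset correlation alone. Glycolysis gave 4 higher and 13 lower of 20 (4 and 13 adjusted over the list alone), camera adjusted p = 0.000202, adjusted p = 0.209 with an estimated correlation. Oxidative phosphorylation gave 1 higher and 20 lower of 26 (1 and 20 adjusted over the list alone), camera adjusted p = 0.000425, adjusted p = 0.288 with an estimated correlation. ALDOA (-0.81) and PGK1 (-0.62) of glycolysis and NDUFB3 (-0.51) of respiratory complex I fell.

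Lysosome genes rose with ipatasertib: 14 of 25 tested members rose and 2 fell (15 and 3 adjusted over the list alone). The lysosome median log2 fold change was 0.257, camera adjusted p = 1.41e-05, adjusted p = 0.0271 with an estimated correlation. The protease gene CTSF rose from 26.7 ± 1.01 to 104 ± 3.69 CPM (log2 fold change 1.97 ± 0.074 SE, edgeR adjusted p = 1.02e-14). Genes reported as silenced by EZH2 in tumours gave 10 higher and 3 lower of 19 (10 and 3 adjusted over the list alone), camera adjusted p = 0.000173, adjusted p = 0.0374 with an estimated correlation. NOV (1.90), MSMB (1.69) and the Wnt antagonist DKK1 (1.30) rose. Luminal mammary markers gave 1 higher and 9 lower of 22 (1 and 9 adjusted over the list alone), camera adjusted p = 0.00598, adjusted p = 0.0585 with an estimated correlation. MUC1 (-0.88) and KRT19 (-0.87) fell. GATA3, a luminal transcription factor, rose from 94.8 ± 8.02 to 132 ± 3 CPM (log2 fold change 0.48 ± 0.074 SE, edgeR adjusted p = 1.62e-05). The basal keratin KRT5 fell from 1720 ± 74.3 to 1170 ± 67.3 CPM (log2 fold change -0.55 ± 0.068 SE, edgeR adjusted p = 9.28e-07), while basal mammary markers as a list did not pass, with 10 higher and 9 lower of 25 (10 and 10 adjusted over the list alone), camera adjusted p = 0.228, adjusted p = 0.281 with an estimated correlation. NF-kB and cytokine genes gave 8 of 13 higher (8 adjusted over the list alone), camera adjusted p = 0.0133, adjusted p = 0.144 with an estimated correlation. Epidermal differentiation genes gave 2 higher and 6 lower of 17 (2 and 6 adjusted over the list alone), camera adjusted p = 0.00181, adjusted p = 0.212 with an estimated correlation. EZH2 itself fell from 118 ± 9.09 to 84.4 ± 1.74 CPM (log2 fold change -0.48 ± 0.074 SE, edgeR adjusted p = 1.63e-05). AKT1 fell (log2 fold change -0.32).

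Among genes that reach 5 CPM in a group without overlap of the replicates, the largest rises with ipatasertib were in PSG5 (3.66), ABTB1 (2.96) and ANKRD1 (2.71) and in the growth factor gene FGF1. The largest falls among them were in CA9, a carbonic anhydrase induced by hypoxia (-3.79), CLCA2 (-2.84), S100A8 (-2.63) and STAC2 (-2.21). By edgeR's quasi-likelihood test, 6864 of 14571 tested genes passed, 3497 higher and 3367 lower, of which 479 rose and 209 fell by a log2 fold change of at least 1. The share of reads outside genes was 3.40 percentage points higher in the ipatasertib libraries than with DMSO, with each ipatasertib library above each DMSO library.

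**Figure D1:**
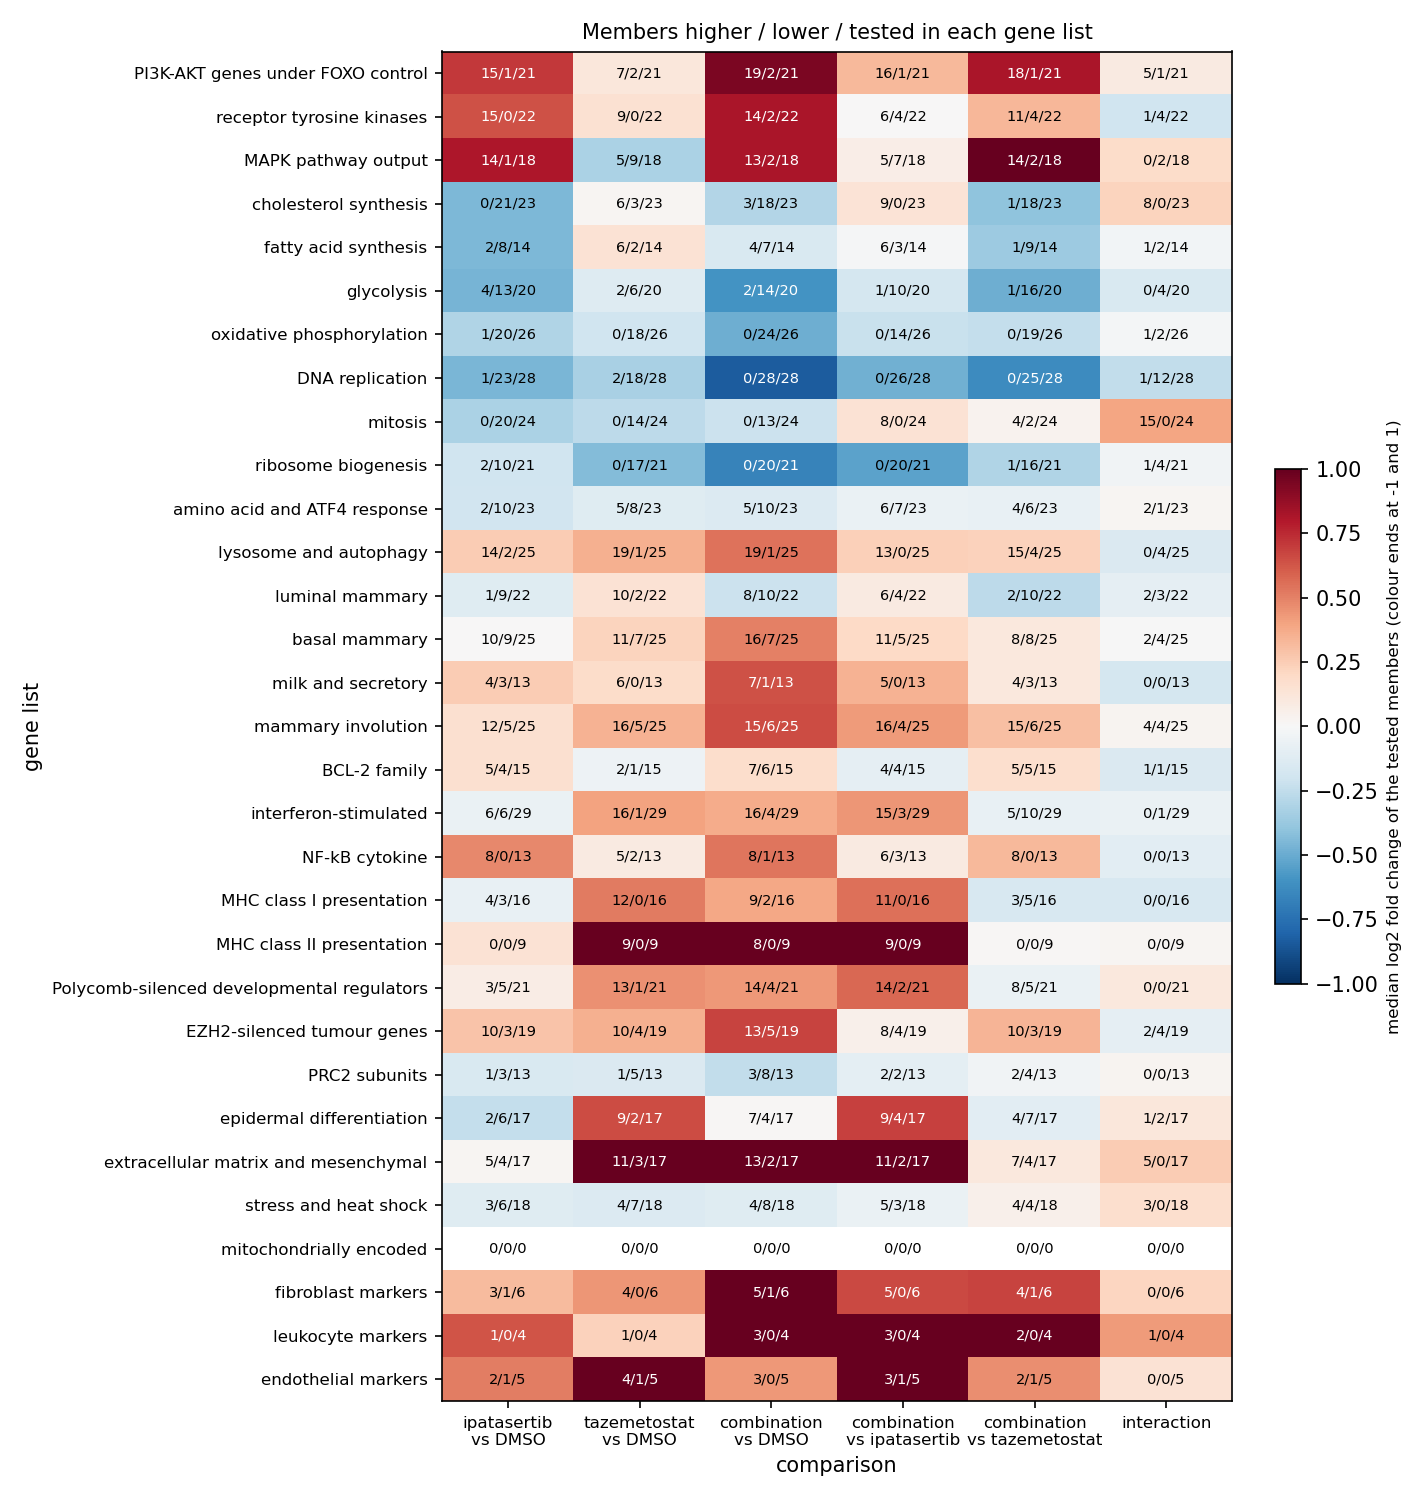
Median log2 fold change of each fixed gene list (lines of the grid) in each comparison (columns of the grid), with the number of members higher and lower in each cell. The DNA replication list was lower in all 28 members with the combination, and the FOXO list was higher in 19 of 21.

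With tazemetostat alone, genes of antigen presentation, of the extracellular matrix and of the lysosome rose, and genes of ribosome production fell. In the MHC class I list, 12 of 16 tested members rose (13 adjusted over the list alone). The MHC class I median log2 fold change was 0.521, camera adjusted p = 1.32e-08, adjusted p = 0.0424 with an estimated correlation. HLA-B rose from 159 ± 1.78 to 569 ± 13 CPM (log2 fold change 1.84 ± 0.071 SE, edgeR adjusted p = 4.99e-15), and HLA-F (1.45) and HLA-C (1.08) rose by smaller log2 fold changes. In the MHC class II list of 13 genes, 9 of 9 tested members rose (9 adjusted over the list alone). The filter removed members with few counts in all groups, so silent members that stayed silent are not counted. The MHC class II median log2 fold change was 2.47, camera adjusted p = 0.000442, adjusted p = 0.0279 with an estimated correlation. These class II genes were weakly expressed: CTSS, the one named here, rose from 4.44 ± 0.294 to 7.99 ± 1.66 CPM (log2 fold change 0.82 ± 0.14 SE, edgeR adjusted p = 3.98e-05). In the extracellular matrix list, 11 of 17 tested members rose and 3 fell (11 and 3 adjusted over the list alone). The matrix median log2 fold change was 1.08, camera adjusted p = 2.29e-08, adjusted p = 0.0051 with an estimated correlation. The basement membrane collagen gene COL4A1 rose from 1.93 ± 0.434 to 26.9 ± 1.95 CPM (log2 fold change 3.80 ± 0.13 SE, edgeR adjusted p = 5.41e-16), and COL4A2 (2.99), FN1 (2.38) and TGFBI (1.68) rose too. Fibroblast markers gave 4 of 6 higher (4 adjusted over the list alone), camera adjusted p = 0.0155, adjusted p = 0.103 with an estimated correlation. Of these, PDGFRA (1.72) is also in the receptor tyrosine kinase list. With tazemetostat, COL3A1 was at 0.45 ± 0.135 CPM (0.0635 ± 0.0157 with DMSO), DCN at 0.329 ± 0.0398 and COL1A2 at 0.0263 ± 0.0229, the last 2 without a read in the DMSO libraries. Endothelial markers did not pass as a list, with 4 higher and 1 lower of 5 (4 and 1 adjusted over the list alone), camera adjusted p = 0.369, adjusted p = 0.536 with an estimated correlation. ESAM (1.17) rose and KDR (-0.55) fell.

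Many genes that were silent with DMSO were expressed after tazemetostat. WBP5 was at 21.9 ± 0.286 CPM with tazemetostat and had no read in any DMSO library, which makes it at least 564-fold higher against a floor of 3 counts over the DMSO group. On the same floor the gap junction gene GJA1 was at least 382-fold higher, ODZ3 at least 322-fold, SHISA2 at least 242-fold and the pluripotency factor SOX2 at least 233-fold. The collagenase gene MMP13 had 1 count over the DMSO libraries and 61.5 ± 9.39 CPM with tazemetostat, a ratio of 4660 with a 95% counting interval of 837 to 184000. Of the 1245 genes that rose by a log2 fold change of at least 1, 824 (66.2%) were under 1 CPM with DMSO, as were 28 of the 80 that fell by as much. The filter removed genes with few counts in all groups, so silent genes that stayed silent are not among those tested. NOV, a secreted matrix protein, rose from 2.79 ± 0.393 to 39.4 ± 4.4 CPM (log2 fold change 3.82 ± 0.11 SE, edgeR adjusted p = 5.29e-17). Developmental regulators known as Polycomb targets gave 13 higher and 1 lower of 21 tested members, of 40 in the list (13 and 1 adjusted over the list alone). Their camera adjusted p was 0.0164, and 0.228 with an estimated correlation. Without the A libraries, a fit chosen after seeing the data, the list's camera adjusted p was 0.104. The EZH2-silenced tumour list did not pass, with 10 higher and 4 lower of 19 (10 and 4 adjusted over the list alone), camera adjusted p = 0.0728, adjusted p = 0.228 with an estimated correlation. EZH2 itself was at 118 ± 9.09 CPM with DMSO and 113 ± 7.02 with tazemetostat (edgeR adjusted p = 0.521).

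Of the lysosome genes, 19 of 25 tested members rose and 1 fell (20 and 1 adjusted over the list alone). The lysosome median log2 fold change was 0.358, camera adjusted p = 3.75e-06, adjusted p = 0.0252 with an estimated correlation. GPNMB, a lysosomal membrane glycoprotein, rose from 88.7 ± 1.6 to 581 ± 19.5 CPM (log2 fold change 2.71 ± 0.064 SE, edgeR adjusted p = 8.27e-19), and CTSD (0.56) and WIPI1 (0.62) rose. In the list of genes of mammary involution, the regression of the gland after lactation, 16 of 25 tested members rose and 5 fell (16 and 5 adjusted over the list alone). The involution median log2 fold change was 0.344, camera adjusted p = 0.00422, adjusted p = 0.0424 with an estimated correlation. BMF, a pro-apoptotic BH3-only gene in that list, rose from 15.4 ± 0.118 to 52 ± 4.88 CPM (log2 fold change 1.76 ± 0.087 SE, edgeR adjusted p = 3.53e-13), as did CTSL1 (1.21) and CP (1.22), whereas SAA1 fell (-1.53). BCL2L11, another BH3-only gene, rose from 40.2 ± 3.22 to 61.8 ± 0.946 CPM (log2 fold change 0.62 ± 0.084 SE, edgeR adjusted p = 2.87e-06). Interferon-stimulated genes gave 16 higher and 1 lower of 29 (17 and 1 adjusted over the list alone), camera adjusted p = 0.000872, adjusted p = 0.0853 with an estimated correlation. IFI44 (1.94), IFIT2 (1.35) and IFIT3 (1.02) rose. Milk and secretory genes gave 6 of 13 higher (6 adjusted over the list alone), camera adjusted p = 0.0153, adjusted p = 0.168 with an estimated correlation. Epidermal differentiation genes gave 9 higher and 2 lower of 17 (9 and 2 adjusted over the list alone), camera adjusted p = 0.00709, adjusted p = 0.28 with an estimated correlation. IVL (1.78) and KLK5 (0.98) rose.

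Of the ribosome biogenesis genes, 17 of 21 tested members fell (17 adjusted over the list alone). The ribosome biogenesis median log2 fold change was -0.436, camera adjusted p = 1.45e-08, adjusted p = 0.0107 with an estimated correlation. MYC fell from 69.3 ± 2.77 to 39.7 ± 2.25 CPM (log2 fold change -0.80 ± 0.070 SE, edgeR adjusted p = 4.3e-09), and RRS1 (-0.96), NOP16 (-0.78) and NOP56 (-0.62) fell too. DNA replication genes gave 2 higher and 18 lower of 28 (2 and 19 adjusted over the list alone), camera adjusted p = 5.62e-05, adjusted p = 0.0514 with an estimated correlation. Mitosis genes gave 14 of 24 lower (14 adjusted over the list alone), camera adjusted p = 0.00283, adjusted p = 0.35 with an estimated correlation. Oxidative phosphorylation genes gave 18 of 26 lower (18 adjusted over the list alone), camera adjusted p = 0.00319, adjusted p = 0.364 with an estimated correlation. MAPK target genes gave 5 higher and 9 lower of 18 (5 and 9 adjusted over the list alone), camera adjusted p = 0.0153, adjusted p = 0.189 with an estimated correlation. IER3 (-1.36) and ETV4 (-1.01) fell. Receptor tyrosine kinase genes gave 9 of 22 higher (9 adjusted over the list alone), camera adjusted p = 0.0331, adjusted p = 0.352 with an estimated correlation. This call was lost without tazemetostat B (adjusted p = 0.0637) or tazemetostat C (0.0552). The basal keratins KRT5 and KRT14 fell, KRT5 from 1720 ± 74.3 to 1020 ± 39.9 CPM (log2 fold change -0.75 ± 0.068 SE, edgeR adjusted p = 8.27e-09) and KRT14 from 220 ± 6.52 to 114 ± 1.38 CPM (log2 fold change -0.94 ± 0.069 SE, edgeR adjusted p = 2.34e-10). Basal mammary markers as a list did not pass, with 11 higher and 7 lower of 25 (12 and 7 adjusted over the list alone), camera adjusted p = 0.181, adjusted p = 0.241 with an estimated correlation. IGFBP5 fell from 197 ± 3.82 to 120 ± 7.7 CPM (log2 fold change -0.72 ± 0.073 SE, edgeR adjusted p = 4.64e-08), and IL22RA2 had the largest fall of the named genes (-2.79). In all, 6874 of 14571 genes passed with tazemetostat, 3775 higher (54.9%) and 3099 lower, with 1245 rises and 80 falls of at least 1 on the log2 scale. With library totals in place of TMM factors the split was 4573 higher (67.9%) and 2159 lower.

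**Figure D2:**
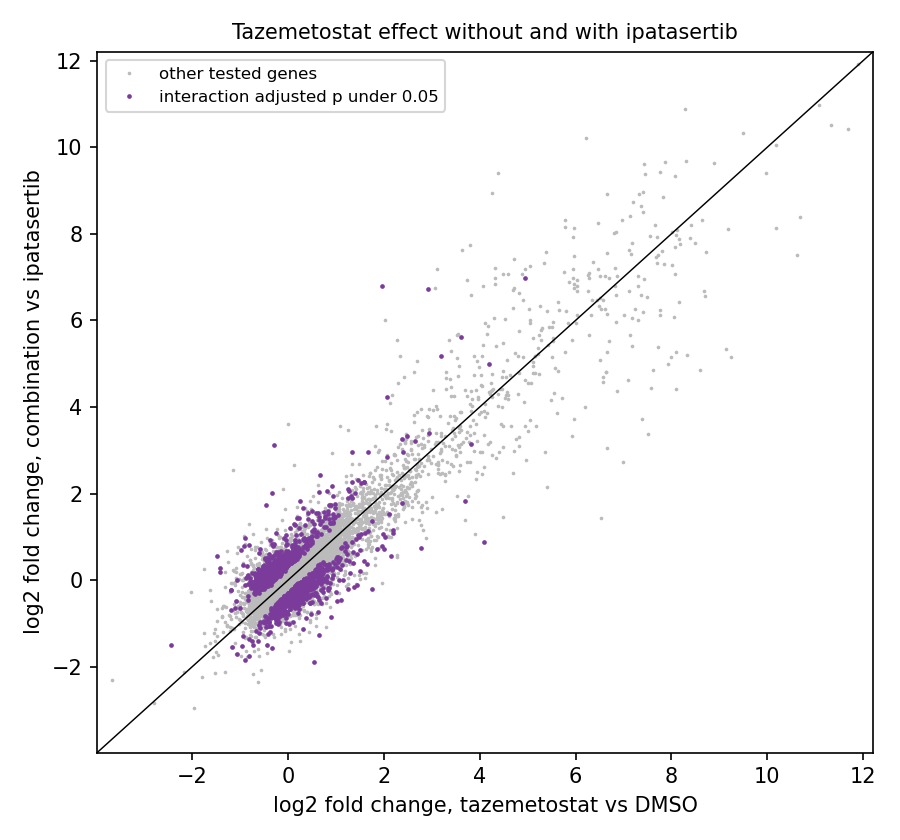
Log2 fold change of each tested gene with tazemetostat alone (against DMSO) and with tazemetostat added to ipatasertib (combination against ipatasertib), one point per gene. Pearson's r across the 14571 genes is 0.912.

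With both drugs, DNA replication and ribosome genes had the lowest list medians, and the FOXO, lysosome and extracellular matrix lists rose. Of the DNA replication genes, 28 of 28 tested members fell (28 adjusted over the list alone). The DNA replication median log2 fold change was -0.831, camera adjusted p = 1.75e-17, adjusted p = 0.0051 with an estimated correlation. E2F1 fell from 85.2 ± 2.01 to 24.5 ± 3.28 CPM (log2 fold change -1.79 ± 0.095 SE, edgeR adjusted p = 4.18e-13), and CDC25A (-1.81), RRM2 (-1.62) and CDC6 (-1.59) fell. Of the ribosome biogenesis genes, 20 of 21 tested members fell (20 adjusted over the list alone). The ribosome biogenesis median log2 fold change was -0.668, camera adjusted p = 4.6e-09, adjusted p = 0.00653 with an estimated correlation. MYC fell from 69.3 ± 2.77 to 30.1 ± 1.78 CPM (log2 fold change -1.20 ± 0.074 SE, edgeR adjusted p = 4.49e-12). In the FOXO list, 19 of 21 tested members rose and 2 fell (19 and 2 adjusted over the list alone). The FOXO median log2 fold change was 0.942, camera adjusted p = 1.86e-13, adjusted p = 0.00603 with an estimated correlation. PIK3IP1 rose from 13.3 ± 1.4 to 140 ± 10.8 CPM (log2 fold change 3.39 ± 0.092 SE, edgeR adjusted p = 3.91e-18) and IRS2 from 28.3 ± 1.58 to 134 ± 11.8 CPM (log2 fold change 2.24 ± 0.077 SE, edgeR adjusted p = 2.21e-16). In the extracellular matrix list, 13 of 17 tested members rose and 2 fell (13 and 2 adjusted over the list alone). The matrix median log2 fold change was 1.31, camera adjusted p = 1.59e-09, adjusted p = 0.00606 with an estimated correlation. TGFBI rose from 7.12 ± 0.722 to 56.2 ± 3.91 CPM (log2 fold change 2.98 ± 0.10 SE, edgeR adjusted p = 2.88e-16). Of the lysosome genes, 19 of 25 tested members rose and 1 fell (19 and 1 adjusted over the list alone). The lysosome median log2 fold change was 0.546, camera adjusted p = 1.12e-06, adjusted p = 0.0252 with an estimated correlation. GPNMB rose from 88.7 ± 1.6 to 872 ± 22.1 CPM (log2 fold change 3.30 ± 0.066 SE, edgeR adjusted p = 2.94e-20).

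Of the involution genes, 15 of 25 tested members rose and 6 fell (15 and 6 adjusted over the list alone). The involution median log2 fold change was 0.652, camera adjusted p = 0.00294, adjusted p = 0.0376 with an estimated correlation. BMF rose from 15.4 ± 0.118 to 58.4 ± 3.08 CPM (log2 fold change 1.93 ± 0.089 SE, edgeR adjusted p = 3.35e-14), CTSL1 (2.37) and SOCS3 (1.46) rose, and S100A8 (-1.94) fell. GATA3 rose from 94.8 ± 8.02 to 189 ± 15.7 CPM (log2 fold change 0.99 ± 0.074 SE, edgeR adjusted p = 1.24e-10) and JAK1 from 185 ± 5.5 to 335 ± 15.3 CPM (log2 fold change 0.85 ± 0.065 SE, edgeR adjusted p = 1.69e-10). STAT3, a mediator of involution, was at 292 ± 6.26 CPM with DMSO and 284 ± 11.1 with the combination (edgeR adjusted p = 0.631). The basal keratin KRT5 fell from 1720 ± 74.3 to 443 ± 35.7 CPM (log2 fold change -1.96 ± 0.070 SE, edgeR adjusted p = 4.4e-16). KRT14, another basal keratin, fell by a log2 fold change of -1.38. Neither mammary marker list passed. Basal markers gave 16 higher and 7 lower of 25 (camera adjusted p = 0.124). Luminal markers gave 8 higher and 10 lower of 22 (camera adjusted p = 0.276). The EZH2-silenced tumour list gave 13 higher and 5 lower of 19 (13 and 5 adjusted over the list alone), camera adjusted p = 0.000375, adjusted p = 0.0565 with an estimated correlation. NOV (5.04) and DKK1 (2.77) rose. MHC class I gave 9 higher and 2 lower of 16 (9 and 2 adjusted over the list alone), camera adjusted p = 0.00371, adjusted p = 0.223 with an estimated correlation. Class II gave 8 of 9 tested members higher, of 13 in the list (8 adjusted over the list alone), camera adjusted p = 0.014, adjusted p = 0.0853 with an estimated correlation. Without the A libraries the class II adjusted p was 0.0567.

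Several lists passed against DMSO only with the preset correlation. Receptor tyrosine kinase genes gave 14 higher and 2 lower of 22 (14 and 2 adjusted over the list alone), camera adjusted p = 5.5e-05, adjusted p = 0.115 with an estimated correlation. MAPK target genes gave 13 higher and 2 lower of 18 (14 and 2 adjusted over the list alone), camera adjusted p = 0.000892, adjusted p = 0.0853 with an estimated correlation. Cholesterol synthesis gave 3 higher and 18 lower of 23 (3 and 18 adjusted over the list alone), camera adjusted p = 0.00779, adjusted p = 0.104 with an estimated correlation. Glycolysis gave 2 higher and 14 lower of 20 (2 and 14 adjusted over the list alone), camera adjusted p = 3.88e-05, adjusted p = 0.168 with an estimated correlation. Oxidative phosphorylation gave 24 of 26 lower (24 adjusted over the list alone), camera adjusted p = 7.73e-06, adjusted p = 0.209 with an estimated correlation. NF-kB and cytokine genes gave 8 higher and 1 lower of 13 (8 and 1 adjusted over the list alone), camera adjusted p = 0.0164, adjusted p = 0.189 with an estimated correlation. Interferon-stimulated genes gave 16 higher and 4 lower of 29 (16 and 4 adjusted over the list alone), camera adjusted p = 0.0457, adjusted p = 0.225 with an estimated correlation. The call was lost without combination C (adjusted p = 0.0578). Mitosis genes gave 13 of 24 lower (12 adjusted over the list alone), camera adjusted p = 0.0457, adjusted p = 0.499 with an estimated correlation. Their call was lost without DMSO A (0.0531), without combination A (0.155) and without all 4 A libraries (0.189). Fibroblast markers gave 5 higher and 1 lower of 6 (5 and 1 adjusted over the list alone), camera adjusted p = 0.00716, adjusted p = 0.0974 with an estimated correlation. COL1A2 was at 0.0369 ± 0.064 CPM with the combination, COL3A1 at 0.256 ± 0.0666 and DCN at 0.141 ± 0.0861. Leukocyte markers did not pass (3 of 4 higher (3 adjusted over the list alone), camera adjusted p = 0.0565, adjusted p = 0.28 with an estimated correlation). PTPRC was at 0.601 ± 0.0992 CPM and CD74 at 0.757 ± 0.133, and CSF1R rose from 3.28 ± 0.452 to 19.1 ± 1.37 CPM (log2 fold change 2.53 ± 0.12 SE, edgeR adjusted p = 5.42e-14). The share of reads outside genes was 5.35 percentage points above DMSO, the depth of the group was the lowest of the 4, and each combination library held fewer reads in genes than each DMSO library. In all, 9389 genes passed, 5018 higher and 4371 lower, with 1860 rises and 426 falls of at least 1 on the log2 scale. Against the floor of 3 counts over the DMSO group, SHISA2 was at least 688-fold higher, WBP5 at least 572-fold and RGS7 at least 278-fold.

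**Figure D3:**
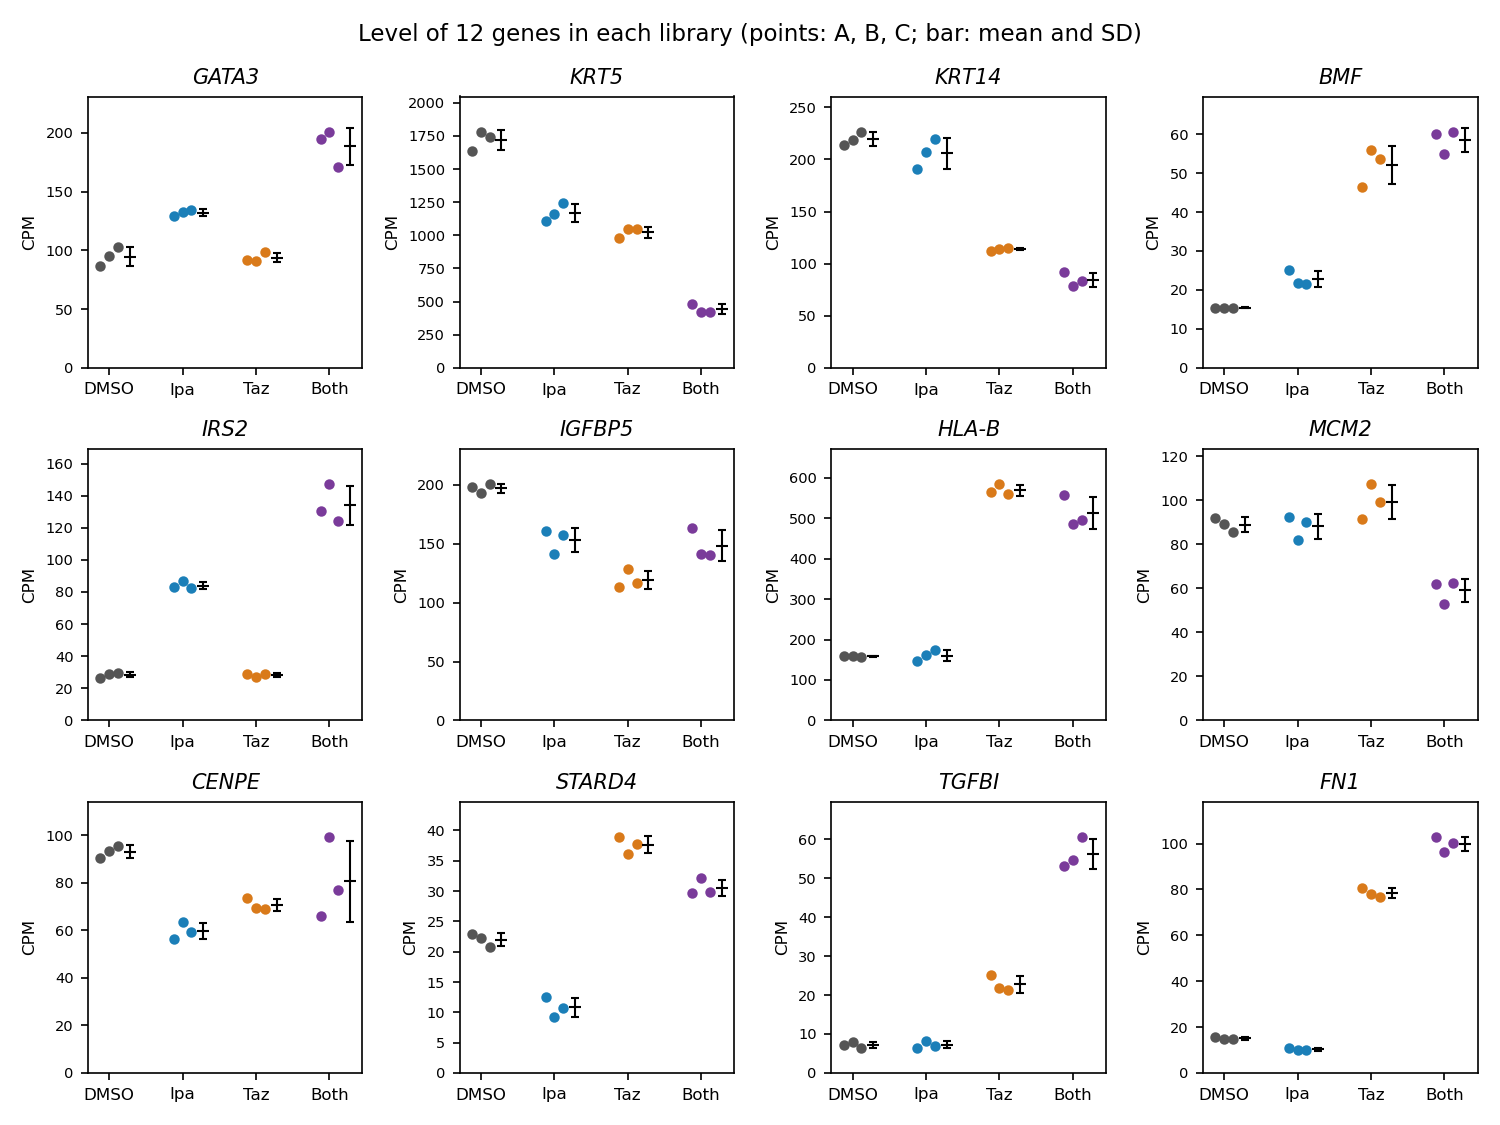
Level (CPM) of 12 named genes in each of the 12 libraries, with the mean and SD of each group of 3. KRT5 fell from 1720 ± 74.3 with DMSO to 443 ± 35.7 with the combination and BMF rose from 15.4 ± 0.118 to 58.4 ± 3.08.

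Adding tazemetostat to ipatasertib lowered DNA replication and ribosome genes and raised extracellular matrix and involution genes. Of the DNA replication genes, 26 of 28 tested members fell (27 adjusted over the list alone). The DNA replication median log2 fold change was -0.483, camera adjusted p = 1.36e-10, adjusted p = 0.0127 with an estimated correlation. CDC25A (-1.04) and MCM10 (-0.85) fell. Of the ribosome biogenesis genes, 20 of 21 tested members fell (20 adjusted over the list alone). The ribosome biogenesis median log2 fold change was -0.537, camera adjusted p = 4.51e-11, adjusted p = 0.0051 with an estimated correlation. MYC fell from 101 ± 2.97 to 30.1 ± 1.78 CPM (log2 fold change -1.75 ± 0.074 SE, edgeR adjusted p = 1.58e-14). In the extracellular matrix list, 11 of 17 tested members rose and 2 fell (11 and 2 adjusted over the list alone). The matrix median log2 fold change was 1.26, camera adjusted p = 5.44e-12, adjusted p = 0.0051 with an estimated correlation. FN1 rose from 10.3 ± 0.633 to 99.8 ± 3.25 CPM (log2 fold change 3.27 ± 0.078 SE, edgeR adjusted p = 8.5e-19). Fibroblast markers moved with them, with 5 of 6 higher (6 adjusted over the list alone), camera adjusted p = 0.00399, adjusted p = 0.0723 with an estimated correlation. In the involution list, 16 of 25 tested members rose and 4 fell (16 and 4 adjusted over the list alone). The involution median log2 fold change was 0.428, camera adjusted p = 0.000805, adjusted p = 0.0271 with an estimated correlation. BMF rose from 22.8 ± 2.12 to 58.4 ± 3.08 CPM (log2 fold change 1.36 ± 0.086 SE, edgeR adjusted p = 2.04e-11). MHC class I gave 11 of 16 higher (12 adjusted over the list alone), camera adjusted p = 8.73e-06, adjusted p = 0.0853 with an estimated correlation. Class II gave 9 of 9 tested members higher, of 13 in the list (9 adjusted over the list alone), camera adjusted p = 0.000805, adjusted p = 0.0501 with an estimated correlation. FOXO genes gave 16 higher and 1 lower of 21 (17 and 1 adjusted over the list alone), camera adjusted p = 0.00218, adjusted p = 0.104 with an estimated correlation. PIK3IP1 rose from 61.3 ± 2.98 to 140 ± 10.8 CPM (log2 fold change 1.19 ± 0.081 SE, edgeR adjusted p = 6.37e-11). Developmental Polycomb targets gave 14 higher and 2 lower of 21 tested members, of 40 in the list (16 and 2 adjusted over the list alone). Their camera adjusted p was 0.00564, and 0.185 with an estimated correlation. Without the A libraries the adjusted p was 0.0526. GATA3 rose from 132 ± 3 to 189 ± 15.7 CPM (log2 fold change 0.51 ± 0.074 SE, edgeR adjusted p = 6.22e-06). KRT5 fell from 1170 ± 67.3 to 443 ± 35.7 CPM (log2 fold change -1.40 ± 0.069 SE, edgeR adjusted p = 2.93e-13). Neither mammary marker list passed here. Luminal markers gave 6 higher and 4 lower of 22 (camera adjusted p = 0.509). Basal markers gave 11 higher and 5 lower of 25 (camera adjusted p = 0.354). Cholesterol synthesis gave 9 of 23 higher (9 adjusted over the list alone), camera adjusted p = 0.0457, adjusted p = 0.209 with an estimated correlation. That call was lost without ipatasertib A (0.0653), ipatasertib B (0.0675) or combination A (0.0971). Leukocyte markers gave 3 of 4 higher (3 adjusted over the list alone), camera adjusted p = 0.0299, adjusted p = 0.228 with an estimated correlation. Their call was lost without ipatasertib A (0.0504), combination A (0.0534) or the A libraries (0.142). In all, 6540 genes passed, 3528 higher and 3012 lower.

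Adding ipatasertib to tazemetostat raised FOXO and MAPK genes and lowered lipid synthesis and replication genes. In the FOXO list, 18 of 21 tested members rose and 1 fell (18 and 1 adjusted over the list alone). The FOXO median log2 fold change was 0.818, camera adjusted p = 6.11e-22, adjusted p = 0.0051 with an estimated correlation. IRS2 rose from 28.4 ± 1.12 to 134 ± 11.8 CPM (log2 fold change 2.24 ± 0.077 SE, edgeR adjusted p = 1.28e-15). In the MAPK list, 14 of 18 tested members rose and 2 fell (14 and 2 adjusted over the list alone). The MAPK median log2 fold change was 1.02, camera adjusted p = 5.87e-15, adjusted p = 0.00606 with an estimated correlation. ETV5 (2.15) and ETV4 (1.94) rose. Of the cholesterol synthesis genes, 1 of 23 tested members rose and 18 fell (1 and 18 adjusted over the list alone). The cholesterol synthesis median log2 fold change was -0.403, camera adjusted p = 5.22e-05, adjusted p = 0.0271 with an estimated correlation. SC5DL rose against the direction of the list (0.81). Of the fatty acid synthesis genes, 1 of 14 tested members rose and 9 fell (1 and 9 adjusted over the list alone). The fatty acid synthesis median log2 fold change was -0.36, camera adjusted p = 0.000123, adjusted p = 0.021 with an estimated correlation. SREBF1, which drives this pathway, fell from 160 ± 16.2 to 84.3 ± 10 CPM (log2 fold change -0.93 ± 0.092 SE, edgeR adjusted p = 3.63e-08). Of the DNA replication genes, 25 of 28 tested members fell (25 adjusted over the list alone). The DNA replication median log2 fold change was -0.629, camera adjusted p = 7.11e-18, adjusted p = 0.0051 with an estimated correlation. Luminal markers gave 2 higher and 10 lower of 22 (2 and 10 adjusted over the list alone), camera adjusted p = 0.000481, adjusted p = 0.0252 with an estimated correlation. ELF5 (-2.00) and MUC1 (-1.50) fell. The EZH2-silenced tumour list gave 10 higher and 3 lower of 19 (10 and 3 adjusted over the list alone), camera adjusted p = 0.000219, adjusted p = 0.0423 with an estimated correlation. The extracellular matrix list gave 7 higher and 4 lower of 17 (7 and 5 adjusted over the list alone), camera adjusted p = 0.00125, adjusted p = 0.0331 with an estimated correlation. Markers of other cell types did not pass: fibroblasts gave 4 higher and 1 lower of 6, camera adjusted p = 0.129. Leukocyte markers gave 2 of 4 higher (camera adjusted p = 0.064) and endothelial markers 2 higher and 1 lower of 5 (0.367). Glycolysis gave 1 higher and 16 lower of 20 (1 and 16 adjusted over the list alone), camera adjusted p = 7.88e-08, adjusted p = 0.0892 with an estimated correlation. SOX2 fell from 9.09 ± 1.17 to 0.994 ± 0.548 CPM (log2 fold change -3.11 ± 0.24 SE, edgeR adjusted p = 8.98e-09), and STON1 (3.28) and ANKRD1 (3.63) rose. In all, 6747 genes passed, 3374 higher and 3373 lower.

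The interaction asks whether the effect of ipatasertib differed in the presence of tazemetostat, as (combination minus tazemetostat) minus (ipatasertib minus DMSO) on the log2 scale. Cholesterol synthesis genes were less reduced with both drugs than by the sum of the single effects. With the preset correlation alone, mitosis genes were higher and DNA replication genes lower than that sum. Of the mitosis genes, 15 of 24 tested members were higher (18 adjusted over the list alone). The mitosis median interaction was 0.397, camera adjusted p = 2.81e-12, adjusted p = 0.0704 with an estimated correlation. CENPE, a kinesin of the mitotic spindle, was at 93.2 ± 2.72 CPM with DMSO, 59.8 ± 3.54 with ipatasertib, 70.7 ± 2.63 with tazemetostat and 80.8 ± 17 with both (interaction 0.83 ± 0.14 SE, edgeR adjusted p = 0.00115). Of the DNA replication genes, 1 of 28 tested members were higher and 12 were lower (1 and 15 adjusted over the list alone). The DNA replication median interaction was -0.246, camera adjusted p = 2.49e-05, adjusted p = 0.0501 with an estimated correlation. MCM2, a subunit of the replicative helicase, was at 88.9 ± 3.25, 88.3 ± 5.65, 99.4 ± 7.76 and 59 ± 5.33 CPM in the same order (interaction -0.74 ± 0.11 SE, edgeR adjusted p = 0.000512). Of the cholesterol synthesis genes, 8 of 23 tested members were higher (12, and 3 were lower, adjusted over the list alone). The cholesterol synthesis median interaction was 0.226, camera adjusted p = 0.000254, adjusted p = 0.0424 with an estimated correlation. SC5DL was at 357 ± 15.1, 269 ± 11.6, 419 ± 60.3 and 732 ± 62 CPM (interaction 1.21 ± 0.12 SE, edgeR adjusted p = 4.01e-06).

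GATA3 stood at 94.8 ± 8.02, 132 ± 3, 93.8 ± 3.9 and 189 ± 15.7 CPM with DMSO, ipatasertib, tazemetostat and both, above the sum of the single effects (interaction 0.53 ± 0.10 SE, edgeR adjusted p = 0.00378). IRS2 (interaction 0.67 ± 0.11 SE, edgeR adjusted p = 0.000771) and TGFBI (interaction 1.29 ± 0.15 SE, edgeR adjusted p = 3.83e-05) were above it too. KRT5 was below the sum (interaction -0.65 ± 0.096 SE, edgeR adjusted p = 0.000512). Luminal markers (2 higher and 3 lower of 22, camera adjusted p = 0.224) did not pass as a list. Basal markers (2 higher and 4 lower of 25, camera adjusted p = 0.752) did not pass either. Extracellular matrix genes gave 5 of 17 higher (5 adjusted over the list alone), camera adjusted p = 0.00906, adjusted p = 0.0625 with an estimated correlation. Without the A libraries the matrix adjusted p was 0.0936. FOXO genes gave 5 higher and 1 lower of 21 (7 and 1 adjusted over the list alone), camera adjusted p = 0.014, adjusted p = 0.189 with an estimated correlation. Receptor tyrosine kinase genes gave 1 higher and 4 lower of 22 (1 and 7 adjusted over the list alone), camera adjusted p = 0.00598, adjusted p = 0.229 with an estimated correlation. Glycolysis genes gave 4 of 20 lower (5 adjusted over the list alone), camera adjusted p = 0.00906, adjusted p = 0.346 with an estimated correlation. Lysosome genes gave 4 of 25 lower (6 adjusted over the list alone), camera adjusted p = 0.0167, adjusted p = 0.148 with an estimated correlation. Stress and heat shock genes gave 3 of 18 higher (3 adjusted over the list alone), camera adjusted p = 0.01, adjusted p = 0.104 with an estimated correlation. This last call was lost without combination A (0.0534) and without the A libraries (0.0936). In 53 of 100 regroupings of the same libraries, the real one included, at least 9 lists passed. The regroupings mix the drug groups, so they do not decide whether chance is excluded for the number of lists. By single genes, 1744 of 14571 passed the edgeR test, 869 above and 875 below the sum, and 45 and 42 of them by at least 1 on the log2 scale. With library totals in place of TMM factors, 694 were above and 1369 below, so the share above moved from 49.8% to 33.6%. The count depended on single libraries. It was 945 without DMSO B, 676 without DMSO C, 982 without ipatasertib A, 1036 without ipatasertib C, 714 without tazemetostat B, 889 without tazemetostat C and 674 without combination B. It was 3681 without tazemetostat A and 3231 without combination A, and 5452 without the A library of every group, a fit chosen after seeing the data. The number of mitosis genes above the sum ranged from 10, without DMSO C or tazemetostat C, to 19, without combination A; it was 15 with all libraries. The number of DNA replication genes below the sum was 12 with all libraries, 7 without DMSO A, DMSO C, ipatasertib C or tazemetostat C, and 6 without tazemetostat B or combination B.

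The effect of each drug was compared with and without the other, over contrasts that share no library. The orthogonal slopes were 1.01 for ipatasertib and 1.02 for tazemetostat. Contrasts of equal spread give a slope near 1 at any positive correlation, so these do not show that the effects kept their size. The ordinary slopes on the effect without the other drug were 0.672 and 0.932, and noise in that effect can lower them. Across 14571 genes, which are not independent replicates, the ipatasertib effect without and with tazemetostat had a Pearson's r of 0.666 and a Spearman's rho of 0.639 (r of 0.742 over 13061 genes with a mean of at least 1 CPM). This correlation across genes, effect of ipatasertib without and with tazemetostat, was 0.255 without a filter and 0.338 with DESeq2, so its size depends on the filter. DESeq2 was run over 19877 genes, as was the fit without a filter, so a part played by the tool cannot be told apart. Both contrasts called 2113 genes higher and 1980 lower, against 810 and 779 for independent lists, and 115 genes went opposite ways. IRS2 and PIK3IP1 are among those higher in both. The tazemetostat effect without and with ipatasertib had an r of 0.912 and a rho of 0.635 (correlation across genes, effect of tazemetostat without and with ipatasertib, 0.651 without a filter and 0.718 with DESeq2), with 2472 genes higher and 1492 lower in both, against 914 and 641 for independent lists, and 153 opposite. HLA-B, FN1 and BMF are among those higher in both.

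The effects of ipatasertib and tazemetostat against the same DMSO libraries had 1473 genes higher in both, including CTSF and GPNMB, and 1580 lower in both, including KRT5, CDK1 and IGFBP5. Another 707 went opposite ways, including MYC, which rose to 101 ± 2.97 CPM with ipatasertib and fell to 39.7 ± 2.25 with tazemetostat, and KLK6. Independent lists would share 906 and 716. With library totals in place of TMM factors, 1950 were higher and 1086 lower in both, so the balance of shared rises and falls depends on the scaling. Among 13061 genes with a mean of at least 1 CPM, the r between the fold changes was 0.248, against 0.482 in 20 simulations of unchanged groups against these controls. These simulations hold no drug effect, so their r reflects noise alone and is no measure for the observed r. The covariance was 0.0926, against 0.00763 in simulation, a difference of 0.085. By simulation the spread between the shared control libraries thus gave a small part of the covariance. An offset common to the 3 DMSO libraries was not simulated, so its part is not known. The highest number of shared calls in any simulation was 0, against 3053 observed. Unchanged groups give few calls, so that number does not size the part of the overlap due to shared controls. The 3 DMSO libraries cannot be split into parts of at least 2, so part of the excess overlap may come from the shared controls.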

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

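Tests chosen only after the result was seen were the rise of the same genes against ipatasertib, the test of the least raised marker of each cell type, the scaling test of the mitosis genes, the tests of genomic DNA and of unspliced RNA, the fit without the A libraries, and the spread asked of the scaling, GC and depth tests, which was set after their first values, as was the reading of splits that call nothing. The genomic DNA test was changed to use coding length besides transcript length after its first value (15.3%) was seen, and the scaling test of the mitosis genes replaced one whose value does not move with the factors. The other tests were chosen before.

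The interaction, a test of whether the ipatasertib effect differs with tazemetostat present, drew attention to 1744 genes and 9 gene lists. Among named genes the most positive interactions (log2) were in FKBP9L (2.05), BCAT1 (2.02), SEMA6A (2.005), NEXN (1.87), CLEC2B (1.63) and C2CD4A (1.59). CLEC2B lost its call without DMSO B (edgeR adjusted p = 0.153), and FKBP9L shares sequence with FKBP9, which leaves it uncertain. The most negative were in SNCAIP (-1.56), MGAT5 (-1.28), RHBDL3 (-1.275), GPR124 (-1.25), ATP2A3 (-1.21) and ALDH3A1 (-1.15). Of the panel, GATA3 (0.53), IGFBP5 (0.67) and IRS2 (0.67) were above the sum of the single effects and KRT5 (-0.65) below. BMF (-0.40) and KRT14 (-0.34) were below as well. The BMF call was lost without DMSO A (0.0651), DMSO B (0.077), DMSO C (0.0922), ipatasertib A (0.117), tazemetostat B (0.118), tazemetostat C (0.0987) and combination B (0.123). The KRT14 call was lost without DMSO A (0.065), DMSO B (0.0683), DMSO C (0.0582), ipatasertib C (0.0876), tazemetostat B (0.0642), tazemetostat C (0.0729), combination B (0.114) and combination C (0.0586).

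In the lists, SESN3 (0.60), SC5DL (1.21), STARD4 (0.72), CENPE (0.83), TOP2A (0.74), TGFBI (1.29), FN1 (0.89), HSPE1 (0.97) and HSP90AA1 (0.54) were above the sum. TYRO3 (-0.65), FGFR1 (-0.50), PFKL (-0.59), PFKM (-0.46), MCM2 (-0.74), CCNE1 (-0.66), CTSF (-0.55) and CTSD (-0.49) were below it. FGFR1 lost its call without combination B (edgeR adjusted p = 0.0598). PFKM lost it without DMSO B (0.0555), DMSO C (0.0809), ipatasertib C (0.0539), tazemetostat B (0.0516), tazemetostat C (0.0813) and combination B (0.087). In reads that no comparison used, the share outside genes was 3.40 percentage points above DMSO with ipatasertib and 5.35 with the combination. Groups of 3 were not tested for single outlying libraries.

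With tazemetostat, 1245 genes rose and 80 fell by a log2 change of at least 1. Few counts are argued against, since 91.2% of such changes were rises (176 against 17) among genes with a mean of at least 10 CPM. Scaling beyond the methods tried stays open: a shift of 0.54 would make rises and falls equal in number. That shift ranged from 0.5 to 0.57 when 1 library was left out, too near the bound of 0.5 set for excluding it. The choice among the methods is argued against, in a reading made after the result was seen. RLE factors moved the fold changes by a median of -0.0092 and library totals by 0.0716 (log2). Fibroblasts, leukocytes or endothelium as the whole cause are argued against: with 2 SE added, the least raised abundant marker of each type (COL1A2, PTPRC and PECAM1) rose by at most 0.103 CPM, against a riser median of 2.2 CPM; other cell types stay open, as the median of all 8 markers (0.248 CPM) missed the bound set beforehand and COL3A1, DCN, CD74 and VWF were raised. As a hypothesis, release of silent genes by the EZH2 inhibitor may account for the pattern, but no test here decides it. Of the risers, 91.2% were also higher in the combination against ipatasertib, which shares no library with tazemetostat against DMSO. That shows that the rises repeat with tazemetostat, and any effect of the drug would give it. Developmental Polycomb targets passed with the preset correlation alone (camera adjusted p = 0.0164, 0.228 with an estimated correlation). The EZH2-silenced tumour list did not pass (camera adjusted p = 0.0728, 0.228 with an estimated correlation).

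With the preset correlation alone, mitosis genes were higher with both drugs than the sum of the single effects (camera adjusted p = 2.81e-12, adjusted p = 0.0704 with an estimated correlation). The A libraries are argued against, since 19 members passed above the sum (1 below) without them. GC content and transcript length stay open. The median was 0.397 (SE 0.0639) before and 0.251 (SE 0.0418) after a fit on both, which explained 13.5% of the variance. Both SEs treat the members as independent. The estimated correlation between members was 0.272, so these SEs are too small to decide. Scaling beyond the methods tried stays open. A shift of 0.397 (0.355 to 0.458 with 1 library left out) would bring the list median to 0. It would bring the median of all genes to -0.413, and it is under the bound of 0.5 for excluding scaling. The choice among the methods is argued against, in a reading made after the result was seen. RLE factors moved the interaction by a median of 0.00276 over the genes and library totals by -0.0538. More cells in G2 and mitosis relative to S phase may also underlie it, but cell cycle phase was not measured. In a second G2 and mitosis list 12 of 24 genes were above the sum (median 0.366, range 0.138 to 0.831). That list holds genes of the same kind in the same libraries, so any cause acting on them would give it. The mitosis list did not pass for the combination against ipatasertib (camera adjusted p = 0.324) or tazemetostat (0.992). Chance stays open: of 100 splits of the libraries, 1, the real one, gave as many members (15, highest other 0), but the others mix groups that differ in many genes and 99 of 99 called no member, so they decide nothing.

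The share of reads outside genes, those assigned to no counted feature, was higher with ipatasertib and with both drugs. Genomic DNA stays open: reads in 370 olfactory receptor genes rose from 1.28 to 3.62 CPM of all counted reads, 37.1% (SE 8.12) by coding length, or 15.3% (SE 3.36) by transcript length, of what an even spread of the added reads over the genome gives. Depth stays open: within groups the share and the total had an r of 0.268 and a rho of 0.301 (exact permutation p = 0.484 and 0.456 over 1296 reorderings; 0.114 for r without the 2 farthest libraries). More unspliced or unannotated RNA with ipatasertib may also underlie it, with 4.08 points between the combination and tazemetostat (lowest combination library 24.34%, highest tazemetostat library 22.97%). These explanations cannot be told apart here, because the share follows the groups.

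Other splits of the same libraries were refitted. For the counts of genes, 1 of 10 splits, the real one, gave as many in each pairwise comparison (real 6864, 6874, 9389, 6540 and 6747 in the order of the report, highest other 0 each); 10 splits are too few for a share under 0.05. For the interaction, 2 of 100 splits gave as many as the real 1744, but 97 of the 99 other splits called no gene, since mixing the groups puts the drug effects into the residual spread. They do not decide whether chance is excluded, and the count runs from 674 without combination B to 3681 without tazemetostat A. The other of the 2 gave 3703 genes and set the libraries without tazemetostat against those with it, which points to the structure of the groups; the next highest gave 1. For the gene lists, adjusted within each comparison, 1, 1, 2, 1 and 1 of 10 splits gave as many (real 14, 16, 19, 17 and 15, highest other 13, 13, 20, 16 and 13), again too few splits. For the interaction lists, 53 of 100 splits gave as many as the real 9, with 21 as the highest other. These splits mix the drug groups too, so drug effects can enter the contrast and they do not decide on chance. Chance is not excluded for that number of lists.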

How the results depend on the processing

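The fit without the A library of every group was chosen after seeing the data; all other alternatives were planned. No result that passed reversed its direction in any alternative run; 59 values of named genes and 39 of lists that passed in neither fit changed sign. The counts of the 5 pairwise comparisons stayed within 1.5 times their values with RLE factors, library totals, DESeq2, either filter, the 2 groups alone, the replicate block and each library left out. The interaction count of 1744 was 1012 (533 above, 479 below) with the replicate block, 674 to 3681 with 1 library left out and 5452 without the A libraries; the cause was not tested. DESeq2 gave 2153 and library totals 2063. Same-letter deviations of ipatasertib and DMSO had correlations of 0.13 to 0.45, each over the bound of 0.1 for pairing (own letter best in 1 of 3), and the block ended no call of a named gene or list there. In no other comparison did all letters pass the bound, so they were not taken to pair the other groups or the libraries of the interaction. The correlations were -0.058 to 0.096 for tazemetostat and DMSO, and -0.64 to -0.37 for the combination and tazemetostat. They were -0.26 to -0.049 for the combination and DMSO. For the combination and ipatasertib they were -0.41 to 0.38, and letter B (0.38) matched its own letter best. The block took the ipatasertib count from 6864 to 6345. It ended the calls of 5 of 52 named interaction genes (BMF 0.0752, KRT14 0.0625, PFKM 0.0535, SLC2A1 0.0837, CTGF 0.0819), of 1 of 85 named genes in the combination against ipatasertib (KRT18, 0.0652) and of 1 list there.

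Gene lists past camera numbered 14, 16, 18, 17, 15 and 9 in the order of the report. With an estimated correlation these were 8, 6, 6, 4, 8 and 1. With fry, which does not compare a list with other genes, they were 26, 28, 30, 29 and 23 for the pairwise comparisons. Leaving out 1 library ended 1 list call with tazemetostat, 2 in each of the combination against DMSO and against ipatasertib, and 1 in the interaction. With calls of at least 1 on the log2 scale, shared calls fell to 398 for the ipatasertib effect without and with tazemetostat, 1034 for the tazemetostat effect and 166 for the overlap of the drugs, by construction. The correlation across genes, effect of ipatasertib without and with tazemetostat, was 0.666; it was 0.255 without a filter, 0.338 with DESeq2, 0.748 with the strict filter and 0.615 to 0.664 with 1 library left out. The correlation across genes, effect of tazemetostat without and with ipatasertib, was 0.912; it was 0.651 without a filter, 0.718 with DESeq2 and 0.896 to 0.912 with 1 library left out. The correlation across genes, overlap of ipatasertib and tazemetostat calls, was 0.194 and ranged from 0.146 to 0.259. These moved by more than their SD over the libraries left out in 14 of 19, 13 of 19 and 8 of 16 alternatives; the cause was not tested. Named genes kept their calls in every alternative run for 85 of 87 with ipatasertib, 84 of 85 with tazemetostat, 115 of 118 with the combination, 83 of 85 and 94 of 94 against the single drugs, and 40 of 52 in the interaction.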

Other observations

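No test in this part was chosen after its result was seen. PRC2, the complex that carries EZH2, did not pass as a list. With ipatasertib it gave 1 higher and 3 lower of 13 (1 and 3 adjusted over the list alone), camera adjusted p = 0.315, adjusted p = 0.365 with an estimated correlation. With tazemetostat it gave 1 higher and 5 lower of 13 (1 and 5 adjusted over the list alone), camera adjusted p = 0.254, adjusted p = 0.328 with an estimated correlation. With both it gave 3 higher and 8 lower of 13 (3 and 8 adjusted over the list alone), camera adjusted p = 0.226, adjusted p = 0.295 with an estimated correlation. With both drugs EZH2 fell from 118 ± 9.09 to 75.2 ± 5.79 CPM (log2 fold change -0.65 ± 0.075 SE, edgeR adjusted p = 1.34e-07), EED fell (-0.53) and EZH1 rose from 9.83 ± 0.705 to 17 ± 1.23 CPM (log2 fold change 0.78 ± 0.11 SE, edgeR adjusted p = 2.31e-06). The BCL-2 family, which sets the threshold of apoptosis, did not pass either. Ipatasertib gave 5 higher and 4 lower of 15 (6 and 4 adjusted over the list alone), camera adjusted p = 0.51, adjusted p = 0.61 with an estimated correlation. Tazemetostat gave 2 higher and 1 lower of 15 (2 and 1 adjusted over the list alone), camera adjusted p = 0.809, adjusted p = 0.857 with an estimated correlation. Both gave 7 higher and 6 lower of 15 (7 and 6 adjusted over the list alone), camera adjusted p = 0.647, adjusted p = 0.733 with an estimated correlation. Basal mammary markers moved both ways, with 16 higher and 7 lower of 25 (16 and 7 adjusted over the list alone), camera adjusted p = 0.124, adjusted p = 0.218 with an estimated correlation for the combination. There LAMB3 (1.81) and VIM (1.63) rose while KRT5 (-1.96) fell.

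Amino acid and ATF4 response genes gave 5 higher and 10 lower of 23 (5 and 10 adjusted over the list alone), camera adjusted p = 0.124, adjusted p = 0.352 with an estimated correlation with both drugs. Stress and heat shock genes gave 4 higher and 8 lower of 18 (4 and 8 adjusted over the list alone), camera adjusted p = 0.367, adjusted p = 0.483 with an estimated correlation. Milk and secretory genes gave 7 higher and 1 lower of 13 (7 and 1 adjusted over the list alone), camera adjusted p = 0.192, adjusted p = 0.364 with an estimated correlation. MFGE8, a milk fat globule protein, rose (0.70). Endothelial markers gave 3 of 5 higher (3 adjusted over the list alone), camera adjusted p = 0.25, adjusted p = 0.427 with an estimated correlation. PECAM1 was at 0.0717 ± 0.0698 CPM and VWF at 0.355 ± 0.0904 with both drugs, and at 0.351 ± 0.154 and 0.254 ± 0.076 with DMSO (SD, n = 3). The cell cycle inhibitor CDKN1C rose with both drugs (log2 fold change 1.16 ± 0.13 SE, edgeR adjusted p = 7.8e-08). AKT1 fell from 184 ± 3.66 to 121 ± 10.4 CPM (log2 fold change -0.61 ± 0.072 SE, edgeR adjusted p = 1.82e-07).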
